A study of Mus musculus with 4 samples.

How the data were processed

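Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map EBF1 in A-MuLV (Abelson murine leukemia virus) transformed mouse pro-B cells. The series has 4 libraries: 1 EBF1-wt ChIP, 1 EBF1-H240A ChIP and 1 input (sheared chromatin without precipitation) for each. Every library was grouped by its title. Peak tables of the 2 ChIP libraries were analysed; the inputs entered only through the values the peak caller derived from them. With 1 library per condition there is no replicate error, so no test between conditions was made and no p-value is given for any difference.

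Per the labels' protocols, crosslinked chromatin was sonicated to an average of 300 bp, and libraries were amplified for 10 PCR cycles without size selection. Per the submitters' processing notes, bcl2fastq 1.8.4, Bowtie2, SAMtools, Picard, MACS2 2.1.0.20150731 and HOMER 4.6 were used with the mm9 build; the role and settings of each, including duplicate removal, are not given in the sources used here. Per the file headers, each peak has a 1-based start, end and summit, a summit pileup, a p-value and q-value on the −log10 scale, and a fold enrichment. The pileup is a coverage signal at the summit, as deposited by the authors. The deposited −log10 p-values and q-values are those of the peak caller for each peak. The deposited fold enrichment is a ratio of the summit pileup to a local background. These are the authors' values. They were used to describe, rank and filter peaks and to compare ranks between the lists, and the pileups and folds also gave the relative depth and the counts expected from depth. Peaks were listed separately for each library. Lowest deposited −log10 q-values were 2.06 for EBF1-wt and 2.01 for EBF1-H240A. No interval was duplicated and no intervals within a list overlapped.

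Total read numbers are not given in the sources used here, and relative depth was worked out from the tables. The deposited EBF1-wt pileups were multiples of 0.635, with 97.0% of distinct values whole within 0.005, whereas all EBF1-H240A pileups were whole numbers. Dividing the EBF1-wt pileups by that step gave fragments at the summit. The local background was recovered as (pileup + 1) / fold − 1. It had a lowest value of 1.88 in the EBF1-wt list and 1.32 in the EBF1-H240A list. Of the EBF1-wt values above the floor 46.9% were whole numbers, and of the EBF1-H240A values 48.2% were multiples of 0.765, within 0.002. Others were multiples of those steps times the shortest peak (190 bp and 228 bp) over 1000 bp. Together with the floor, both kinds of step held 84.5% and 82.7% of backgrounds, against 2.54% and 2.79% of evenly spread values; the rest fell on no such step. Under MACS2's scaling of the larger library to the smaller, the EBF1-wt input had 0.635 times the reads of its ChIP, the EBF1-H240A ChIP had 0.765 times the reads of its input, and the EBF1-wt ChIP had 2.71 times the reads of the EBF1-H240A ChIP. The ratio of 2.71 assumes the same genome size setting in both runs. It also takes the shortest peak of each list (190 bp and 228 bp) as the fragment length of that run.

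Peaks were called shared when their intervals had at least 1 bp in common, computed in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6; bedtools 2.31.1 gave the same counts. Shares carry 95% Wilson intervals and summit fragments exact 95% Poisson intervals (scipy 1.17.1); both cover counting error only, and PCR reads are not independent molecules. The chance overlap came from 1000 rotations of the EBF1-H240A peaks along their chromosomes. Shared peaks were paired 1 to 1 by largest overlap. Groups of neighbouring peaks were chained where summits lay within 20 kb. Scripts were tested on simulated peak lists, and 8 of 8 simulated quantities were recovered. The depth ratio of the ChIP libraries and the counts expected from depth were not among them.

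Before the data were examined, the overlap rule, its alternatives and the peaks to be named were fixed: the 10 tallest shared peaks by EBF1-wt fold, and the 10 tallest EBF1-wt-only and EBF1-H240A-only peaks by fold in their own list. Alternatives were a 50% reciprocal overlap, summits within 100 bp, gaps of up to 200 bp, a −log10 q of at least 10, equal list lengths and main chromosomes only. Groups of neighbouring peaks, chromosome backgrounds and neighbour tests were added after seeing the data. The tables pair no peak with a gene, and the gene table at hand is for GRCm38, whose coordinates differ from mm9. Peaks are therefore named by mm9 position; the location, EBF1 motif and 10 fixed gene-list comparisons were not run.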

Results

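EBF1 (early B-cell factor 1), a transcription factor required for B-cell development, was mapped by ChIP-seq in a transformed mouse pro-B cell line. The cells carry a conditional Ebf1 allele and a tamoxifen-activated Cre recombinase. Wild-type EBF1 (EBF1-wt) or the substitution mutant EBF1-H240A was supplied from a retrovirus that also encodes GFP. Deletion of the endogenous gene was induced with 2 μM 4-hydroxytamoxifen, started 24 h after transduction; the tables do not measure how complete it was. The tables held 4422 peaks for EBF1-wt and 2759 for EBF1-H240A. There was 1 ChIP library per protein, so none of the differences below has a replicate check. The EBF1-wt library was 2.71 times as deep as the EBF1-H240A library by the scaling in the tables. Its peaks had a median of 49 fragments at the summit (range 18 to 322), against 25 (10 to 320) for EBF1-H240A.

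The first comparison asked whether EBF1-H240A peaks were called at the same sites as EBF1-wt peaks. Most EBF1-H240A peaks had an EBF1-wt counterpart: 2250 of 2759 EBF1-H240A peaks (81.6%, 95% Wilson interval 80.1 to 83.0) overlapped an EBF1-wt peak. In the other direction, 2252 of 4422 EBF1-wt peaks (50.9%, 49.5 to 52.4) overlapped an EBF1-H240A peak, leaving 2170 EBF1-wt-only and 509 EBF1-H240A-only peaks. Random rotation of the EBF1-H240A peaks gave a median of 3 overlapped EBF1-wt peaks and at most 11 in 1000 draws. Rotation ignores any uneven spread of possible sites common to both lists, so a low value was likely in any case. Among 2244 peaks paired 1 to 1, the summits lay a median of 21 bp apart, and 84.2% were within 50 bp. Both shares were higher when only stronger peaks were counted against the full other list: at a −log10 q of at least 10, 60.2% of EBF1-wt and 90.5% of EBF1-H240A peaks were overlapped. With equal numbers of top peaks from each list, the shares were 65.2% in each direction. Endogenous EBF1 left after deletion was not measured, so the overlap does not show that the mutant itself was bound at every shared site.

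The tallest EBF1-wt sites were nearly all called for EBF1-H240A too, and overlap was lower at lower peaks. In the top decile of EBF1-wt fold enrichment (20.6 to 59.5), 435 of 443 peaks (98.2%, 96.5 to 99.1) overlapped an EBF1-H240A peak. In the sixth decile the share was 47.3% (42.7 to 51.9), and over the lower 4 deciles it was 27.6% (25.6 to 29.8). EBF1-H240A peaks showed the same order at higher levels, from 55.8% (49.9 to 61.5) in the lowest decile to 99.3% (97.4 to 99.8) in the highest. The Wilson intervals of the lowest and highest deciles did not overlap in either list. EBF1-wt-only peaks had a median fold of 7.05 and a median width of 248 bp, and shared EBF1-wt peaks 12.1 and 338 bp. EBF1-H240A-only peaks had a median fold of 6.37 and width of 270 bp, and shared EBF1-H240A peaks 9.88 and 350 bp.

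**Figure D1:**
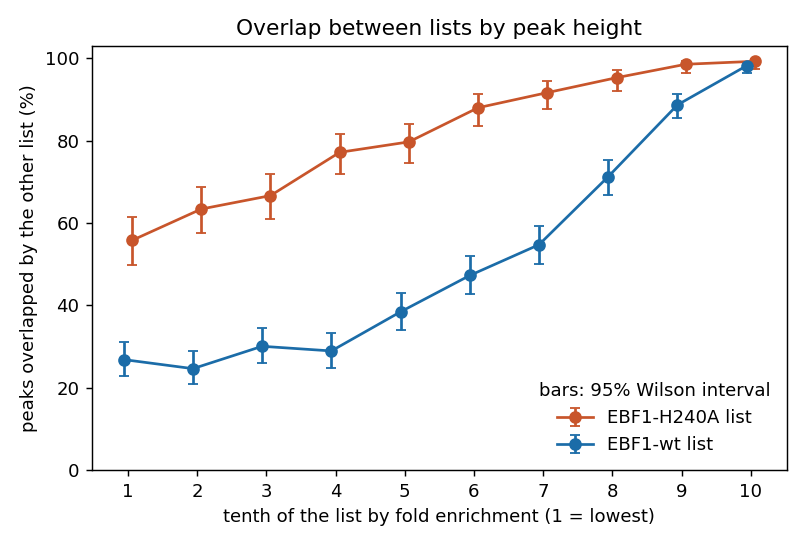
Percentage of peaks overlapped by the other list (vertical axis) in each decile of fold enrichment within a list (horizontal axis, 1 lowest); points are shares, bars are 95% Wilson intervals. The EBF1-wt list goes from 26.9% in the lowest decile to 98.2% in the highest, and the EBF1-H240A list from 55.8% to 99.3%.

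The 10 tallest shared sites, by EBF1-wt fold, were found on chromosomes 2, 3, 5, 7, 8, 9, 14 and 16 (mm9). The tallest spanned 116210805 to 116211275 on chromosome 3, with 59.5-fold enrichment and 306 fragments at the summit (272.7 to 342). It was followed by 122283709 to 122284597 on chromosome 5 (56.4-fold) and 25052047 to 25052532 on chromosome 2 (54.5-fold). Chromosome 8 held sites at 108861799 to 108862442 (52.3-fold) and 108146945 to 108147376 (49.7-fold). Further sites lay at 10522886 to 10523325 on chromosome 16 (48.5-fold), 108526303 to 108526790 on chromosome 7 (48.5-fold) and 57286746 to 57287346 on chromosome 14 (48.3-fold). Chromosome 9 had sites at 120495652 to 120496067 (48.0-fold) and 103390959 to 103391816 (47.4-fold). Among the 2244 pairs, 8 of these 10 sites were also in the upper 224 by EBF1-H240A fold. The chromosome 5 site ranked 2 of 2244 for both proteins. Both chromosome 9 sites ranked lower for EBF1-H240A, at 227 and 434.

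Heights of shared sites were related but not identical between the proteins. Across the 2244 pairs, which are not independent replicates, Spearman's rho of the fold values was 0.62. Of the 224 tallest pairs for each protein, 128 (57.1%) were tallest for both, against 22.4 if the rankings were independent. The tallest EBF1-H240A peak, at 118994939 to 118995583 on chromosome 11, had 127-fold enrichment and 320 fragments at the summit. Its EBF1-wt partner, at 118994877 to 118995515, ranked 158 of 2244 by fold, with 29.3-fold enrichment and 322 fragments. Both fragment counts were the highest of their list. They are not equal signals, because depth and fragment length predicted 0.443 EBF1-H240A fragments per EBF1-wt fragment. Both parts of the fold are on a different scale in each list. The pileup was 204 in the EBF1-wt list, where each fragment counts 0.635, and 320 in the EBF1-H240A list, where each counts 1. The local background, which enters each fold as its denominator, was 6.00 and 1.53. Medians on autosomes other than chromosome 17 were 2.47 and 1.74.

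**Figure D2:**
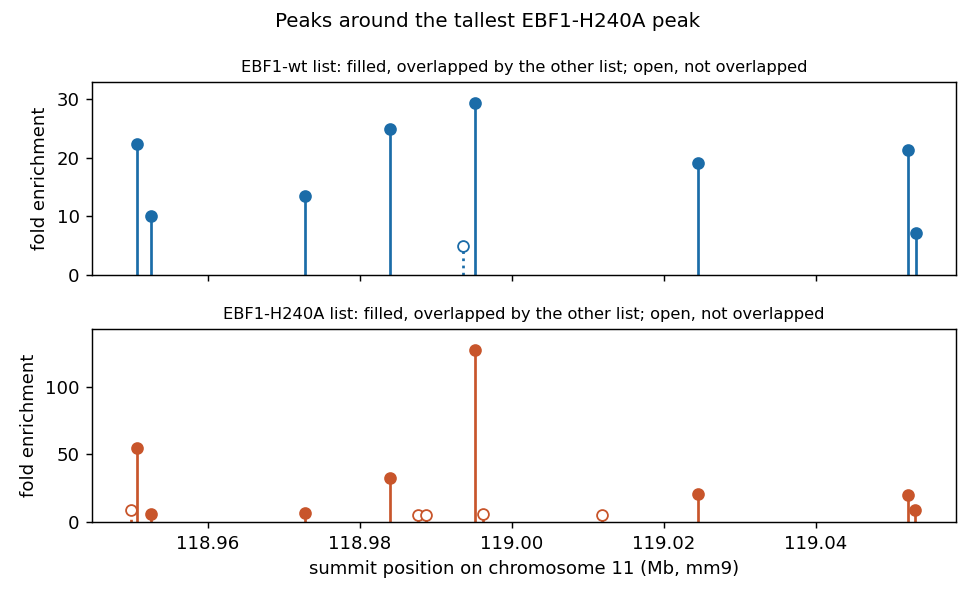
Fold enrichment (vertical axes, a separate scale per panel) at each peak summit around the tallest EBF1-H240A peak on chromosome 11 (horizontal axis, mm9) in the EBF1-wt list (upper) and EBF1-H240A list (lower); filled points overlap the other list and open points do not. The tallest point is 29.3-fold in the EBF1-wt panel and 127-fold in the EBF1-H240A panel, at the same place.

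Peaks called for EBF1-wt alone were lower than shared peaks as a group, and a small part of them was tall. The EBF1-H240A library was the shallower, so a missing call there does not show that a site was unoccupied. Of the 2170 EBF1-wt-only peaks, 97.3% were in the lower 8 deciles of fold, which held 3537 of all 4422 EBF1-wt peaks. The top 2 deciles had 58 of them. The lower 4 deciles, with 1769 of the 4422 peaks, had 59.0% of them. Many were clear calls, as 1329 (61.2%) had a −log10 q of at least 10, although 89.4% of shared EBF1-wt peaks did. The tallest was at 68090097 to 68090608 on chromosome 15, with 28.9-fold enrichment and 139 fragments (117 to 164) at the summit; the nearest EBF1-H240A summit was 31164 bp away. The second, at 137704875 to 137705197 on chromosome 6, had 27.4-fold enrichment and no EBF1-H240A summit closer than 1223867 bp. Chromosome 18 held 2 of the 10 tallest, at 33954314 to 33954729 (24.8-fold) and 24007079 to 24007392 (21.5-fold). Others were at 125533050 to 125533407 on chromosome 5 (23.5-fold), 26202635 to 26202988 on chromosome 7 (23.0-fold) and 98196816 to 98197312 on chromosome 9 (20.8-fold). Chromosome 2 held sites at 167602718 to 167603189 (22.1-fold) and 127163693 to 127164047 (18.8-fold), and chromosome 4 a site at 82970128 to 82970524 (19.7-fold). The second chromosome 2 site lay 2956 bp from an EBF1-H240A summit.

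Of the 509 sites listed for EBF1-H240A alone, 6 were in the top 2 deciles of that list. They were fewer than the 2170 EBF1-wt-only peaks of the full lists; with equal numbers of top peaks from each list, which forces nearly equal counts, there were 959 EBF1-H240A-only and 961 EBF1-wt-only peaks. The tallest were at 87786868 to 87787248 on chromosome 7, with 26.9-fold enrichment and 71 fragments (55.5 to 89.6), and at 3435019 to 3435486 on chromosome 11, with 26.7-fold enrichment and 77 fragments (60.8 to 96.2). The nearest EBF1-wt summits were 128444 bp and 126215 bp away. Next came 62567941 to 62568304 on chromosome 13 (19.4-fold), 57231215 to 57231646 on chromosome 16 (18.6-fold) and 113256390 to 113256773 on chromosome 6 (17.9-fold). The others were 45310294 to 45310656 on chromosome 17 (17.5-fold), 133096533 to 133096896 on chromosome 1 (15.3-fold) and 20701993 to 20702402 on chromosome 16 (14.9-fold). Chromosome 4 held 117947151 to 117947528 (15.1-fold) and 40720917 to 40721256 (14.6-fold).

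Sites listed for a single protein often lay near sites of the other. An EBF1-wt summit was found within 10 kb of 24.8% (21.2 to 28.7) of the 509 EBF1-H240A-only peaks, against a median of 3.14% and at most 6.09% after rotation. An EBF1-H240A summit was found within 10 kb of 15.3% (13.9 to 16.9) of the 2170 EBF1-wt-only peaks, against 1.98% and at most 3.41%. Rotation keeps the grouping of peaks within a list but not the grouping common to both lists.

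A small part of the peaks of both proteins lay in dense regions, and most peaks stood alone. Chaining summits within 20 kb gave 19 regions with at least 5 EBF1-wt peaks and 10 with at least 5 EBF1-H240A peaks. They held 110 of 4422 EBF1-wt and 55 of 2759 EBF1-H240A peaks. By contrast, 61.5% and 68.0% of peaks had no other summit of their list within 20 kb. In 200 random placements there were at most 1 and 0 such regions, but random placement ignores any uneven spread of possible sites along the genome. The fullest EBF1-wt region, 28233996 to 28292334 on chromosome 7, held 8 EBF1-wt peaks, of which 4 were shared. The region from 137117038 to 137167192 on chromosome 5 held 7, of which 6 were shared, and the region from 114232959 to 114282951 on that chromosome held 7, of which 5 were shared. The region from 59347990 to 59395631 on chromosome 10 also held 7, of which 4 were shared. Some EBF1-wt regions had few or no EBF1-H240A peaks. All 5 EBF1-wt peaks between 135409518 and 135416190 on chromosome 5 (up to 14.1-fold) and all 5 between 90727486 and 90761516 on chromosome 16 (up to 6.82-fold) were EBF1-wt-only. In the region from 98607305 to 98656701 on chromosome 11, 1 of 6 EBF1-wt peaks was shared. The fullest EBF1-H240A region, 118972578 to 119024760 on chromosome 11, held 8 EBF1-H240A peaks including the tallest of that list, and 4 were shared.

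The extreme chromosomes of each list were picked from 19 autosomes for their overlap, so their intervals do not test a difference between chromosomes. Among autosomes, the overlapped share of EBF1-wt peaks ran from 40.3% (32.4 to 48.8) on chromosome 18 to 56.2% (50.2 to 62.0) on chromosome 17, where the deciles of fold of their peaks gave 46.6% and 49.8%. For EBF1-H240A peaks it ran from 74.9% (68.4 to 80.4) on chromosome 17 to 86.2% (81.1 to 90.1) on chromosome 5, where the deciles gave 77.7% and 82.2%. The value from the deciles lay inside each interval except that of EBF1-wt on chromosome 17. Chromosome X held 41 EBF1-wt and 20 EBF1-H240A peaks. The local background of the peak caller was higher at chromosome 17 peaks in both lists, with medians of 3.59 against 2.47 on the other autosomes for EBF1-wt and 2.63 against 1.74 for EBF1-H240A. Without chromosome 17, the overlapped shares were 50.6% and 82.1%.

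**Figure D3:**
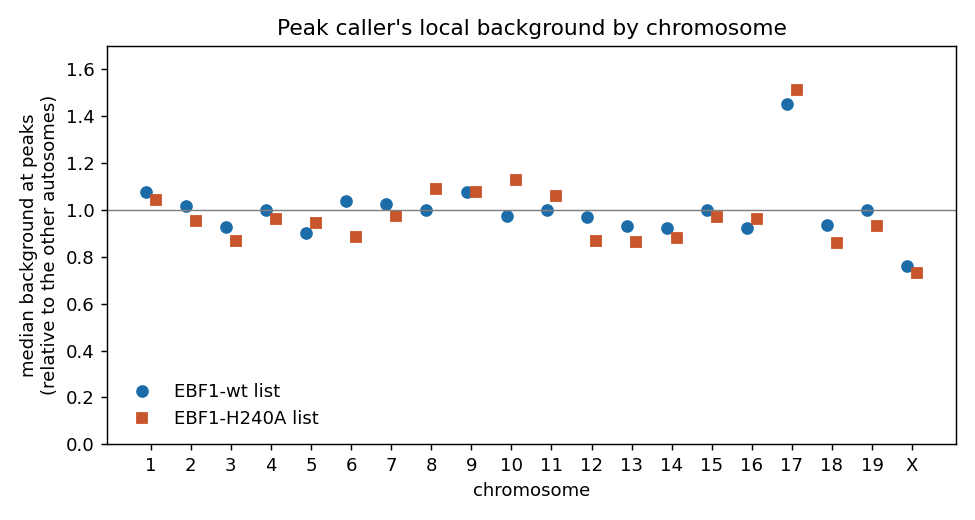
Median local background at peaks of each chromosome divided by the median at peaks of the other autosomes (vertical axis), by chromosome (horizontal axis), for the EBF1-wt (circles) and EBF1-H240A (squares) lists. Chromosome 17 stands at 1.45 and 1.51, the other autosomes between 0.857 and 1.13, and chromosome X at 0.763 and 0.732. On chromosome X, 68.3% and 70% of peaks had the lowest background of their list, so its ratios sit at the lower limit of this measure.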

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

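The main limits are 1 library per protein, a 2.71-fold difference in ChIP depth, and peaks listed separately for each library. Of 45 alternative values, 27 stayed within the interval of the main value or within 1.5 times the main count, and 18 moved. The overlapped share of EBF1-wt peaks (50.9%) became 49.3% with 50% reciprocal overlap, 49.2% with summits within 100 bp, 49.4% with a −log10 q of at least 10 in both lists, 60.2% with that limit only in the list counted, and 65.2% with equal list lengths. The share of EBF1-H240A peaks (81.6%) became 79.0%, 78.8%, 85.1%, 90.5% and 65.2% in the same order. EBF1-wt-only peaks (2170) fell to 1329 with the limit in the list counted and 961 with equal lengths. EBF1-H240A-only peaks (509) fell to 290 with the limit in both lists and 184 in the list counted, and were 959 with equal lengths, so the excess of EBF1-wt-only peaks was absent there, as equal lengths require. Ranking by −log10 q moved the overlapped share of the top decile of EBF1-wt peaks from 98.2% to 99.1%, that of the lowest decile from 26.9% to 19.4%, and rho from 0.62 to 0.69. Keeping only the 4287 EBF1-wt peaks whose summit count would still pass at the EBF1-H240A depth, a setting chosen after seeing the data, as was leaving out chromosome 17, gave 52.1% and 2054 EBF1-wt-only peaks. The planned location, motif and gene-list alternatives gave no value, because peaks were not tied to mm9 sequence or genes. No paired analysis was possible because each group has a single library.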

Other observations

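Several shared sites ranked far apart for the 2 proteins; they were picked for that difference after seeing the data, and no replicate bears on them. The site at 71291855 to 71292272 on chromosome 14 ranked 276 of 2244 by EBF1-wt fold, with 117 fragments at the summit, and 2190 by EBF1-H240A fold, with 14. The site at 40069586 to 40070025 on chromosome 10 ranked 97 and 1932, with 155 and 21 fragments. The EBF1-wt and EBF1-H240A backgrounds were 2.00 and 2.29 at the chromosome 14 site and 2.00 and 2.62 at the chromosome 10 site. Each fold has its background as denominator, so these ranks reflect background as well as fragments. The next largest shifts in this direction were on chromosomes 15, 19 and 5, with EBF1-H240A backgrounds of 3.06, 3.82 and 3.06. Their EBF1-wt backgrounds were 2.28, 1.90 and 2.11. Backgrounds of the 2 lists are on different scales, with medians on autosomes other than chromosome 17 of 2.47 for EBF1-wt and 1.74 for EBF1-H240A. In the other direction, the largest shift was at 144944840 to 144945120 on chromosome 5. This site ranked 2101 by EBF1-wt fold and 73 by EBF1-H240A fold, with 59 and 85 fragments. Its background was 6.00 in the EBF1-wt list and 1.32 in the EBF1-H240A list. The next largest shifts in that direction were on chromosomes 8, 11 and 6. Their EBF1-wt backgrounds all lay above the median of 2.47, and their EBF1-H240A backgrounds were 1.74, 1.60 and 1.32. A further chromosome 11 site, at 60873107 to 60873466, followed them. It ranked 1691 by EBF1-wt fold, with 47 fragments, and 60 by EBF1-H240A fold, with 106 fragments in the shallower library. Its background was 2.85 in the EBF1-wt list and 1.74 in the EBF1-H240A list, near the medians of 2.47 and 1.74. At the median pair, the EBF1-H240A count was 0.441 of the EBF1-wt count, and depth and fragment length predicted 0.443; at the median of the 225 pairs with the most EBF1-wt fragments it was higher, at 0.505. These ratios cover only sites called in both lists, which leaves out the 2170 EBF1-wt peaks with no EBF1-H240A call and can raise the ratio at low peaks, so the closeness of 0.441 to 0.443 is no check on the depth prediction.

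The tests in the paragraphs that follow were all chosen after the results were seen.

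More peaks were called for EBF1-wt alone than for EBF1-H240A alone (2170 against 509), and how much of this follows from the greater depth of the EBF1-wt library stays open. Scaling EBF1-wt summit counts to the EBF1-H240A depth, Poisson counting alone would miss 354 of the 4422 EBF1-wt peaks, and 2170 were missing. The missing peaks were not all weak: 58 were in the top 2 deciles of fold, where counting alone would miss 0.00023 (expected counts of at least 29.2, with at most 20 needed for a call), and 127 in the eighth decile, where the median was 71 fragments. These predictions cover counting error only. The spread between libraries of 1 protein is not known, and every peak was selected on its own EBF1-wt signal, an effect that was not measured, so the excess over the predictions does not exclude depth with ordinary variation between libraries. A changed preference of EBF1-H240A for some sites, differences in precipitation or in the inputs, and differences between the 2 cell populations may each contribute; they stay open, untested, with 1 library per protein.

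The higher background on chromosome 17 appeared in both lists, which draw on separate inputs, and crowding of peaks as the whole cause was argued against, because at peaks with no neighbour within 50 kb the ratio to other autosomes was still 1.33 for EBF1-wt (95% bootstrap interval 1.27 to 1.42) and 1.33 for EBF1-H240A (1.32 to 1.59). On this measure the other autosomes ran from 0.835 to 1.15 (chromosome 9) and from 0.877 to 1.26 (chromosome 10). The bootstrap intervals rest on 1 input library per list and do not measure variation between libraries. From 20 to 80 Mb the ratio was 1.62 for EBF1-wt (1.46 to 1.62) and 1.60 for EBF1-H240A (1.51 to 1.75). By 20 Mb bins within it, the ratios were 1.62, 1.62 and 1.33 for EBF1-wt and 1.63, 1.51 and 1.62 for EBF1-H240A. This window was chosen after the ratios were seen, so they do not test a gain there. Below 20 Mb the ratio was 0.810 and 1.15 (19 and 14 peaks). Beyond 80 Mb it was 0.931 (0.810 to 1.15) and 1.00 (0.877 to 1.20), which argues against a gain of the whole chromosome. A candidate explanation is a gain of the part from 20 to 80 Mb in the cell line, shared by both replacement populations; the same ratios would follow from a local mapping or GC effect, which was not tested without the mm9 sequence. Peaks from 20 to 30 Mb on chromosome 9 also had raised ratios, 1.54 over 25 peaks and 1.75 over 19.

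Neighbouring EBF1-wt peaks tended to be shared or unshared together. Of 217 neighbours with summits within 2 kb, 61.8% had the same class, against a median of 51.2% after shuffling classes within deciles of fold; 2 of 1000 shuffles were as high. Shuffling within deciles of −log10 q or of summit fragments, or within 50 strata of any of these measures, gave at most 2 of 1000 as high, which argues against peak height, by these measures, as the whole cause. Leaving out neighbours whose intervals were under 500 bp apart gave 61.5% of 135, reached by at most 15 of 1000 shuffles over the same groupings, which argues against a broad region called as adjacent peaks. Beyond 2 kb the excess was smaller: 52.9% against 49.9% of 431 neighbours from 2 to 10 kb apart (71 of 1000 shuffles within deciles of fold were as high) and 51.8% against 50.3% of 973 from 10 to 50 kb apart (166 of 1000). Among 119 EBF1-H240A neighbours within 2 kb the share was 73.9% against 68.9%, reached by 105 of 1000 shuffles; what the EBF1-wt neighbours have in common, including local differences between the inputs, was not tested.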
